A study of Arabidopsis thaliana with 12 samples.

How the data were processed

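The series holds 12 RNA-seq libraries of 14-day-old Arabidopsis thaliana seedlings grown at 22 °C, from the wild type Col and the mutant line cbfs-1, each sampled before cold and after 3 h and 24 h at 4 °C, with 2 libraries per group. The groups and replicate numbers were taken from the sample titles. The deposited table holds signal values, which the authors made by dividing gene read counts by 1 DESeq2 size factor per library, as its name and values show. It has 24616 gene rows and 12 columns, all of which were used. The submitters' processing notes name the TAIR10 build, TopHat2 2.1.0, Cufflinks 2.2.1, HTSeq 0.6.0 and DESeq2 without a version; the role and settings of each tool, the strandedness of the libraries and the counting of reads shared by similar genes are not given in the sources used here. Genes that overlap others, antisense genes and near-identical paralogs such as CBF1, CBF2 and CBF3 therefore have uncertain counts. No row is 0 in all libraries.

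In each column all values were whole multiples of 1 step (100% within a tolerance of 0.001 of a read), so whole reads were recovered by division. The recovered totals ranged from 16849042 to 22800552 reads per library and the size factors from 0.914 to 1.22. The 20 most abundant genes took 11.0% to 13.8% of the reads, and genes of the chloroplast and mitochondrial genomes at most 0.103% and 0.0633%. At this depth 3 reads, taken as the floor, correspond to normalized values of 2.46 to 3.28; genes at or near it are given as levels, not folds. Gene names came from the RefSeq annotation of assembly TAIR10.1, whose coordinates are not printed. It named 24385 of the 24616 loci and left 231 under their locus identifiers.

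As the values are not raw counts, the main test was limma 3.58.1 (lmFit, contrasts.fit and eBayes with a trend) in R 4.3.3 on log2(value + 1), for the 20666 genes with a value of at least 10 in at least 2 libraries. A model of 6 group means over all 12 libraries gave 6 residual degrees of freedom, so the groups of 2 shared 1 estimate of the spread, and no replicate term was used. The replicate numbers come from the labels, which do not say what they share. Deviations of same-numbered libraries from their group means correlated across genes at 0.334 to 0.565 in the 6 pairs of 0 h and 3 h groups, all over 0.1, so within these groups the numbers were taken to pair the libraries, from the data and not from the design. Blocked values stand beside the comparisons of these groups. This block fits 1 replicate term over all 12 libraries, those at 24 h included. A block by time, with a separate term for the 24 h libraries, was chosen after seeing the data and gave more calls in each of these comparisons. Standard errors and adjusted p-values are without a block unless stated. The 9 contrasts were 3 h and 24 h against 0 h in each genotype, cbfs-1 against wild type at each time, and the differences between the genotypes' responses at 3 h and 24 h. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 within a contrast. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 prepared the tables. Overlaps of calls that share wild type libraries were set beside the overlap of independent lists and 100 simulations in which the mutant equalled wild type. Responses of the genotypes were correlated across genes without a p-value.

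The lists, fixed before the data were examined, were CBF family, CBF targets, early cold transcription factors, CBF regulators, circadian clock, light harvesting, flavonoid, sugar and osmolyte, abscisic acid, gibberellin, elongation growth, salicylate and defence, jasmonate, heat shock, RNA chaperones, ribosome biogenesis, membrane lipids, root markers, cell division, floral and seed markers, and reference genes. Of their 239 planned members 232 were used and 7 were left out because the symbol and the locus identifier were not paired in the annotation. Each list was tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, each adjusted over the 21 lists within a contrast. Fry values are given for some lists only, and they differed from camera in both directions. Members were counted with p-values adjusted over all genes and over the list alone. Under the alternatives the same camera test was run, and for edgeR and DESeq2 it was run on z-scores from their p-values.

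The genes named in the text were fixed by rule before the data were examined. They are CBF1, CBF2 and CBF3 always; per contrast the 8 largest rises and 8 largest falls with an adjusted p below 0.05, a mean of at least 100 in the higher group and, for contrasts of 2 groups, both libraries of a group above both of the other; and up to 4 called members per list, with members that did not pass where the text says so. For the cold responses of cbfs-1 only list members are named. Genes named outside the rule are stated as chosen after their values were seen.

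The tests were tried on simulated reads with known changes for cbfs-1 against wild type at 24 h. These reads were drawn independently for each library, without the differences that same-numbered 0 h and 3 h libraries shared. Their rates of calls may therefore not hold for the real libraries. There limma, on 20590 genes, recovered 72% of the 100 genes changed 2-fold and 96% of the 100 genes changed 4-fold, and called 0.0586% of the unchanged genes. On 20666 genes edgeR 4.0.16 recovered 74% and 94% and called 0.0635% of the unchanged genes, and DESeq2 1.42.0 recovered 73% and 94% and called 0.147%. For the difference in the 24 h response limma called 12, edgeR 9 and DESeq2 26 of the unchanged genes. With no change simulated, DESeq2 called 11 genes between the genotypes at 0 h, 14 at 3 h and 8 for the difference in the 3 h response, edgeR 0, 0 and 1, and limma 0 in each.

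The alternatives were pseudocounts of 0.5 and 5, no filter and a filter at 50, TMM scaling, quantile normalization, edgeR's quasi-likelihood test and DESeq2's Wald test on the recovered reads, the replicate number as a block, only the libraries of the compared groups, calls of at least 2-fold, and leaving out each of the 12 libraries in turn. A block by replicate number with separate values for the 24 h libraries was chosen after seeing the data.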

Results

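Gene expression was measured by RNA sequencing in 14-day-old seedlings of Arabidopsis thaliana, in the wild type Col and in the mutant line cbfs-1, before cold and after 3 h and 24 h at 4 °C. Each of the 6 groups held 2 libraries, 12 in all. The recovered read totals per library were 16858218 and 16868905 in wild type at 0 h, 16849042 and 22800552 at 3 h, and 18727639 and 19729206 at 24 h. In cbfs-1 they were 17666511 and 19074773 at 0 h, 18479195 and 19461909 at 3 h, and 17604977 and 21057683 at 24 h. Replicates of a group correlated across genes with Pearson's r from 0.984 to 0.991 on the log2 scale (genes are not independent replicates), and their reads differed by more than sampling noise in all 6 groups (chi-square per degree of freedom 6.30 to 24.6). The labels do not say whether replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. Levels are size-factor-normalized read counts (mean ± SD, n = 2), changes are on the log2(value + 1) scale, which understates changes of low genes, and adjusted p-values are from limma unless another tool is named.

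The genes after which the line is named, CBF1 (AT4G25490), CBF2 (AT4G25470) and CBF3 (AT4G25480), encode cold-induced transcription factors that bind the promoters of cold-regulated genes. In wild type, CBF1 stood at 2.18 and 1.09 at 0 h, 1129 and 2023 at 3 h, and 69.8 and 22.4 at 24 h. In cbfs-1 its values were 1.03 and 1.89, then 1540 and 2475, then 78.7 and 38.1. CBF2 stood at 24.0 and 2.17, 5093 and 6769, and 569 and 239 in wild type, against 63.1 and 12.3, 7570 and 8377, and 941 and 449 in cbfs-1. CBF3 stood at 15.3 and 7.60, 6133 and 7126, and 404 and 180 in wild type, against 175 and 138, 1158 and 1095, and 894 and 799 in cbfs-1. Transcripts of CBF1 and CBF2 were therefore present in the mutant libraries. The nature of the lesion is not given in the sources used here, and a lesion that leaves the transcript in place would not show in gene counts. The 3 genes are close paralogs in tandem, so the division of reads among them is uncertain.

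**Figure D1:**
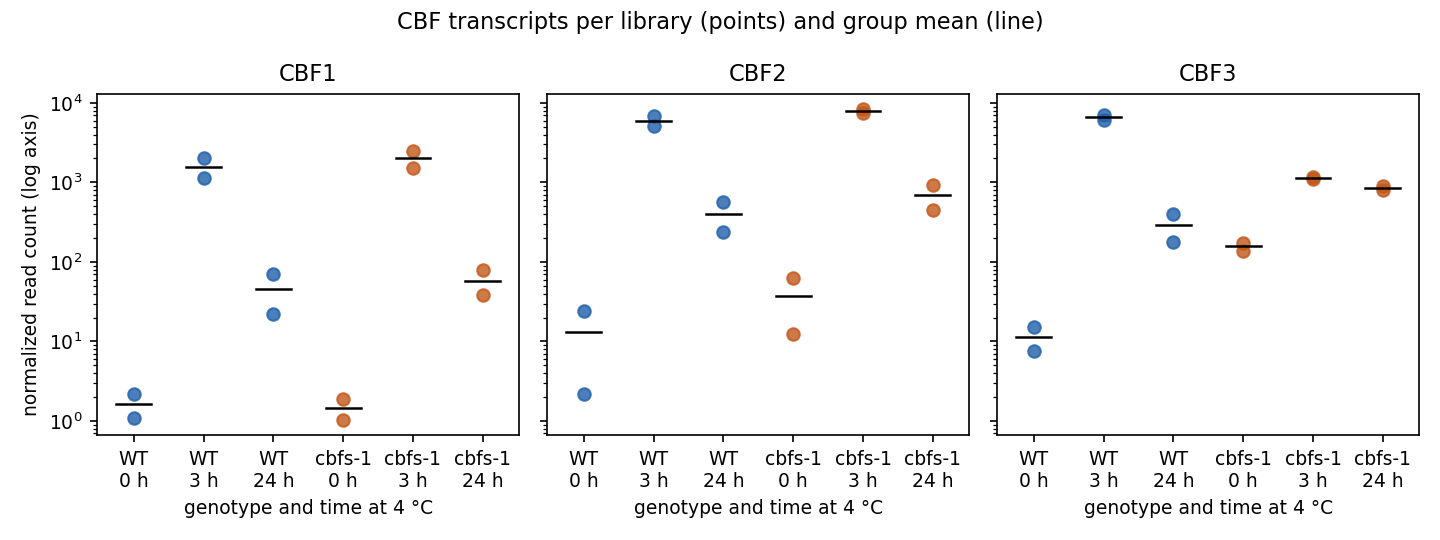
Normalized read counts of CBF1, CBF2 and CBF3 (log axis) in each of the 12 libraries, by genotype and hours at 4 °C; points are libraries and lines are group means. At 3 h the means of wild type and cbfs-1 were 1576 and 2008 for CBF1, 5931 and 7974 for CBF2 and 6629 and 1127 for CBF3.

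The first comparison asked which genes responded to 3 h of cold in wild type. CBF3 rose from 11.4 ± 5.44 to 6629 ± 702 (log2 change 9.13, SE 0.36, adjusted p = 6.45e-06). CBF2 rose from 13.1 ± 15.4 to 5931 ± 1186, and CBF1 from 1.63 ± 0.777 to 1576 ± 632. FKF1, a blue-light receptor of the photoperiod pathway, rose from 7.09 ± 5.42 to 3926 ± 2233. COR27, a cold-regulated gene tied to the clock, rose from 1.63 ± 0.777 to 922 ± 843. The other largest rises were of AT1G70640, a PB1-domain protein gene (1.63 ± 0.762 to 1226 ± 106), of AT4G33980 (2.72 ± 0.782 to 1614 ± 1438) and of the uncharacterized AT4G18422 (2.72 ± 0.757 to 846 ± 50.4). The largest falls were of AT1G14200, a RING-finger gene (log2 change -4.21, SE 0.18), and of LSU1 and LSU3, genes of the low-sulfur response (-3.62, SE 0.45, and -3.30, SE 0.61). AT3G26510, AT3G18773, AT1G04770, AT4G38840 and OXS3 followed, with changes from -3.48 to -3.14.

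Among the gene lists fixed before the data were examined, 12 of 15 CBF target genes rose and 0 fell in wild type at 3 h, with 3 not passing (12 rose when adjusted over the list alone, median log2 change 2.33, camera adjusted p = 2.7e-15, adjusted p = 0.12 with an estimated correlation). COR15B, whose product protects chloroplasts during freezing, rose by 5.40 (SE 0.37), RD29A by 3.47 (SE 0.31), the galactinol synthase gene GOLS3 by 3.42 (SE 0.42) and ERD7 by 3.40 (SE 0.36). All 5 tested members of the CBF family rose (5 when adjusted over the list alone, median 9.13, camera adjusted p = 3.4e-09, adjusted p = 0.063 with an estimated correlation). CBF4 went from 0 in both libraries to 64.8 ± 53.0. All 14 early cold transcription factor genes rose (14 when adjusted over the list alone, median 2.27, camera adjusted p = 8.9e-15, adjusted p = 0.063 with an estimated correlation), among them RVE2 by 4.55 (SE 0.55), the zinc-finger gene ZAT10 by 3.61 (SE 0.68) and ERF6 by 3.05 (SE 0.56). Of 15 regulators of CBF expression, MYB15, SOC1 and CAMTA3 rose, 0 fell and 12 did not pass (5 rose when adjusted over the list alone, camera adjusted p = 0.0016, adjusted p = 0.21 with an estimated correlation). Of 14 circadian clock genes, 7 rose, 0 fell and 7 did not pass (7 rose when adjusted over the list alone, camera adjusted p = 3.7e-05, adjusted p = 0.063 with an estimated correlation), led by PRR5 (7.55, SE 0.38), ELF4 (3.92, SE 0.54), LUX (3.31, SE 0.41) and TOC1 (2.42, SE 0.27).

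Hormone lists moved in part in wild type at 3 h. Of 12 jasmonate genes, 6 rose, 0 fell and 6 did not pass (9 rose when adjusted over the list alone, median 0.75, camera adjusted p = 2.0e-07, adjusted p = 0.063 with an estimated correlation). The repressor gene JAZ1 rose by 2.98 (SE 0.27) and the lipoxygenase genes LOX4 and LOX3 by 2.35 (SE 0.23) and 2.17 (SE 0.21). Of 12 salicylate and defence genes, 4 rose, 0 fell and 8 did not pass (7 rose when adjusted over the list alone, camera adjusted p = 1.2e-04, adjusted p = 0.21 with an estimated correlation): SARD1 by 1.82 (SE 0.25) and CBP60G by 1.71 (SE 0.23), both activators of salicylate synthesis, PAD4 and NPR1. Of 11 gibberellin genes, 4 rose, 2 fell and 5 did not pass (6 rose and 2 fell when adjusted over the list alone, camera adjusted p = 0.092, fry adjusted p = 0.000598). GA2OX1 and GA2OX2, which inactivate gibberellin, rose from 34.3 ± 6.77 to 149 ± 4.48 and from 60.9 ± 16.7 to 139 ± 15.1, whereas GA3OX1, a biosynthesis gene, and the DELLA gene GAI fell (-1.11, SE 0.28, and -0.82, SE 0.19). Of 14 abscisic acid genes, 2 rose and 12 did not pass (4 rose and 1 fell when adjusted over the list alone, camera adjusted p = 0.51). Both encode enzymes that degrade the hormone, CYP707A3 (5.09, SE 0.41) and CYP707A1 (2.02, SE 0.26).

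Of the remaining lists in wild type at 3 h, 2 of 8 RNA chaperone genes rose, GRP7 by 2.33 (SE 0.40) and CSP1 by 0.74 (SE 0.13), with 2 also when adjusted over the list alone (camera adjusted p = 0.092, fry adjusted p = 0.048). In the lists of elongation growth (11 genes), heat shock (7), membrane lipids (10) and sugars and osmolytes (11), 2, 1, 1 and 1 genes rose and 0 fell, and when adjusted over the list alone 4, 1, 1 and 1 rose and 3, 1, 0 and 0 fell (camera adjusted p = 0.95, 0.95, 0.94 and 0.45). These were XTH22 and ATHB2, then DREB2A (3.52, SE 0.40), a regulator of heat and drought genes, then the desaturase gene ADS2 (2.94, SE 0.43), then the beta-amylase gene BAM3 (3.01, SE 0.55). Of 8 cell division genes, PCNA1 fell (-0.60, SE 0.10) and 7 did not pass (1 fell when adjusted over the list alone, camera adjusted p = 0.21). No member passed, adjusted over all genes or over the list alone, among 18 light-harvesting and Rubisco genes, 11 flavonoid, 11 root marker, 6 ribosome biogenesis, 5 reference and 3 floral and seed marker genes (camera adjusted p = 0.88, 0.22, 0.64, 0.94, 0.95 and 0.79). The median was below 0 while the mean and the camera direction were upward for abscisic acid (median -0.15, mean 0.42), heat shock (-0.12, 0.20), membrane lipids (-0.07, 0.26) and floral and seed markers (-0.02, 0.75). For elongation growth (-0.28, -0.04) and ribosome biogenesis (-0.02, -0.01) both were below 0 with an upward camera direction, and for the reference genes (-0.02, 0.01) the camera direction was downward.

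Over the 20666 tested genes, 1423 were higher and 664 lower at 3 h than at 0 h in wild type (10.1% of genes), of which 784 and 257 by at least 2-fold. Without the libraries outside the comparison the counts were 631 and 137, without wild type 3 h replicate 1 they were 712 and 162, without wild type 0 h replicate 2 they were 758 and 201, and without wild type 0 h replicate 1 the lower genes numbered 339. With the replicate number as a block they were 2169 and 1286. No seedlings kept at 22 °C for 3 h were analysed here, so time of day changed together with cold.

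The second comparison asked which genes differed after 24 h of cold in wild type. COR15A, a chloroplast cryoprotectant gene, rose from 357 ± 122 to 81402 ± 14000 (log2 change 7.86, SE 0.38, adjusted p = 1.93e-06), and COR15B from 73.0 ± 34.2 to 29046 ± 2342 (8.70, SE 0.37). RD29A rose from 1165 ± 27.0 to 151190 ± 61530 (6.96, SE 0.31) and GOLS3 from 69.2 ± 16.5 to 12792 ± 8549 (7.35, SE 0.42). COR27 reached 2215 ± 968, AT4G33980 reached 1046 ± 591 and AT1G70640 reached 369 ± 280, and FKF1 reached 1726 ± 689.5. CBF3 was at 292 ± 158, CBF2 at 404 ± 234 and CBF1 at 46.1 ± 33.5, still above 0 h. The largest falls were of the uncharacterized AT1G33055, from 190 ± 12.4 to 0.529 ± 0.748, of the cell wall loosening gene EXPA8 (-5.75, SE 0.61), of the lectin gene AT1G52100 (-5.28, SE 0.38) and of the acyl desaturase gene FTM1 (-5.19, SE 0.20). AT2G29300, AT4G39675, AT5G35777 and AT1G15830 also fell, from 156, 234, 113 and 458 to 3.58, 6.10, 2.56 and 13.8.

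All 15 CBF target genes rose in wild type at 24 h (15 when adjusted over the list alone, median 4.55, camera adjusted p = 4.9e-12, adjusted p = 0.39 with an estimated correlation, fry adjusted p = 3.2e-05). Of 5 CBF family genes, 3 rose and 2 did not pass (4 rose when adjusted over the list alone, camera adjusted p = 0.035, adjusted p = 0.39 with an estimated correlation). Of 14 early cold transcription factor genes, 9 rose, 0 fell and 5 did not pass (9 when adjusted over the list alone, camera adjusted p = 0.0036, adjusted p = 0.39 with an estimated correlation). RVE2 changed by 3.53 (SE 0.55) and ZAT12 by 2.29 (SE 0.27). Of 14 clock genes, 8 rose, 1 fell and 5 did not pass (8 and 1 when adjusted over the list alone, camera adjusted p = 0.018, adjusted p = 0.39 with an estimated correlation). PRR5 rose by 6.41 (SE 0.38), ELF4 by 4.33 (SE 0.54), TOC1 by 3.29 (SE 0.27) and GI by 3.02 (SE 0.44). Of 11 sugar and osmolyte genes, 9 rose, 1 fell and 1 did not pass (9 and 1 when adjusted over the list alone, camera adjusted p = 0.0037, adjusted p = 0.39 with an estimated correlation), including BAM3 (3.94, SE 0.55), the sucrose synthase gene SUS1 (3.51, SE 0.21) and SEX1 (2.60, SE 0.49), which acts in starch breakdown. Of 6 ribosome biogenesis genes, 5 rose and 1 did not pass (5 when adjusted over the list alone, median 1.26, camera adjusted p = 0.0036, adjusted p = 0.39 with an estimated correlation), among them the fibrillarin gene FIB2 (1.55, SE 0.19) and the nucleolin gene NUC1 (1.52, SE 0.12).

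Growth and photosynthesis lists fell in part in wild type at 24 h. Of 11 elongation growth genes, 6 fell, 1 rose and 4 did not pass (6 and 1 when adjusted over the list alone, median -1.19, camera adjusted p = 0.031, adjusted p = 0.39 with an estimated correlation), with XTH15 at -3.65 (SE 0.26), EXPA1 at -2.60 (SE 0.36) and PRE1 at -2.01 (SE 0.33). Of 18 light-harvesting and Rubisco genes, 5 fell, 0 rose and 13 did not pass (5 when adjusted over the list alone, camera adjusted p = 0.023, adjusted p = 0.54 with an estimated correlation), led by LHCB4.2 (-1.74, SE 0.23) and LHCB2.2 (-1.12, SE 0.23). Of 11 root marker genes, 6 fell and 5 did not pass (6 when adjusted over the list alone, camera adjusted p = 0.11), such as CASP1 (-0.96, SE 0.17) and LRX1 (-0.95, SE 0.14). Of 8 cell division genes, 4 fell and 4 did not pass (4 when adjusted over the list alone, camera adjusted p = 0.10), led by CYCD3;1 (-1.07, SE 0.13). Of 11 gibberellin genes, 5 fell, 1 rose and 5 did not pass (5 fell and 2 rose when adjusted over the list alone, camera adjusted p = 0.22). GA20OX1 changed by -1.59 (SE 0.40) and GA2OX6 by 0.94 (SE 0.21). The root marker, cell division and gibberellin genes, which did not pass camera, passed fry (adjusted p = 0.0042, 0.0043 and 0.0016).

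Among the other lists in wild type at 24 h, 6 of 12 salicylate and defence genes rose and 2 fell (6 and 2 when adjusted over the list alone, camera adjusted p = 0.10). SARD1 changed by 1.97 (SE 0.25) and PR5 by 1.94 (SE 0.22). Of 11 flavonoid genes, 5 rose and 2 fell (6 and 2 when adjusted over the list alone, camera adjusted p = 0.33): the chalcone enzyme genes TT5 and TT4 rose by 2.21 (SE 0.48) and 1.96 (SE 0.46), and DFR fell by 1.70 (SE 0.23). Of 12 jasmonate genes, 2 rose and 4 fell (2 and 4 when adjusted over the list alone, camera adjusted p = 0.31). JAZ1 changed by 1.63 (SE 0.27) and VSP2 by -1.62 (SE 0.35). Of 14 abscisic acid genes, 3 rose and 2 fell (3 and 2 when adjusted over the list alone, camera adjusted p = 0.42), with CYP707A1 at 2.98 (SE 0.26) and the phosphatase gene HAI1 at -1.95 (SE 0.44). Of 15 CBF regulators, 6 rose and 3 fell (6 and 3 when adjusted over the list alone, camera adjusted p = 0.28). MYB15 changed by 2.02 (SE 0.31) and PIF4 by -1.79 (SE 0.25). Of 8 RNA chaperone genes, 3 rose and 1 fell (3 and 1 when adjusted over the list alone, camera adjusted p = 0.12), and GRP7 reached 90242 ± 25640. Fry was passed by the salicylate and defence, CBF regulator and RNA chaperone genes (adjusted p = 0.015, 0.025 and 0.0042). It was not passed by the flavonoid, jasmonate and abscisic acid genes (adjusted p = 0.27, 0.064 and 0.24). Heat shock (7 genes) had 1 higher and 2 lower members, DREB2A, HSFA2 and HSP90.1 (1 and 3 when adjusted over the list alone, camera adjusted p = 0.63). Membrane lipids (10 genes) had 2 higher, ADS2 and FAD3, and 1 lower, FAD2 (2 and 1 when adjusted over the list alone, median -0.12, mean 0.35, camera direction downward, adjusted p = 1.00). Of 5 reference genes, UBC21 rose by 0.79 (SE 0.14), GAPC2 fell by 0.44 (SE 0.10) and 3 did not pass (1 and 1 when adjusted over the list alone, camera adjusted p = 0.63), and 0 of 3 floral and seed markers passed, also when adjusted over the list alone (camera adjusted p = 0.45).

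At 24 h 5305 genes were higher and 5022 lower than at 0 h in wild type, of which 1838 and 1933 by at least 2-fold.

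The same comparisons in cbfs-1 asked how the mutant responded to cold. At 3 h CBF1 rose to 2008 ± 661 from 1.46 ± 0.607 and CBF2 from 37.7 ± 35.9 to 7974 ± 571, and CBF3 rose from 157 ± 25.9 to 1127 ± 45.1 (log2 change 2.85, SE 0.36, adjusted p = 0.00135). Of 15 CBF target genes, 9 rose, 1 fell and 5 did not pass (12 rose and 1 fell when adjusted over the list alone, median 1.31, camera adjusted p = 2.7e-08, adjusted p = 0.29 with an estimated correlation). COR15B rose by 4.06 (SE 0.37) and ERD10 by 2.18 (SE 0.27), and RAP2.1, chosen after its value was seen, fell (-1.08, adjusted p = 0.0262). All 5 CBF family genes rose (5 when adjusted over the list alone, camera adjusted p = 3.3e-08, adjusted p = 0.098 with an estimated correlation), with DDF1 going from 0.990 to 21.5. Of 14 early cold transcription factor genes, 11 rose and 3 did not pass (13 when adjusted over the list alone, camera adjusted p = 1.8e-13, adjusted p = 0.087 with an estimated correlation). RVE2 changed by 4.77 (SE 0.55) and CRF3 by 2.84 (SE 0.22). Of 14 clock genes, 7 rose and 7 did not pass (8 when adjusted over the list alone, median 1.46, camera adjusted p = 4.0e-06, adjusted p = 0.042 with an estimated correlation). This was the only camera call, over the 21 lists and 9 contrasts, to pass with an estimated correlation. PRR5 rose by 7.79 (SE 0.38) and ELF4 by 4.50 (SE 0.54).

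Of the hormone lists in cbfs-1 at 3 h, 6 of 12 jasmonate genes rose (6 when adjusted over the list alone, camera adjusted p = 3.8e-06, adjusted p = 0.098 with an estimated correlation). JAZ1 changed by 2.70 (SE 0.27) and JAZ5 by 2.57 (SE 0.34). Of 15 CBF regulators, 4 rose (7 when adjusted over the list alone, camera adjusted p = 0.0052, adjusted p = 0.29 with an estimated correlation), SOC1, MYB15, CAMTA3 and BZR1. Of 11 gibberellin genes, 5 rose and 1 fell (5 and 2 when adjusted over the list alone, camera adjusted p = 0.16, fry adjusted p = 0.00067). GA2OX1 changed by 2.70 (SE 0.21). Of 14 abscisic acid genes, 4 rose (5 rose and 1 fell when adjusted over the list alone, camera adjusted p = 0.26), with CYP707A3 at 5.37 (SE 0.41), and of 12 salicylate and defence genes, 4 rose (4 and 1 when adjusted over the list alone, camera adjusted p = 0.25). SARD1 changed by 1.57 (SE 0.25). Elongation growth, RNA chaperones, heat shock, membrane lipids and sugars and osmolytes had 3, 2, 1, 1 and 1 higher members and 0 lower, and cell division 1 lower, PCNA1; when adjusted over the list alone these were 4, 2, 1, 1 and 1 higher, with 2 elongation growth genes lower, and 1 lower (camera adjusted p = 0.56, 0.12, 0.71, 0.71, 0.71 and 0.26). They included YUC8 (1.17, SE 0.28), GRP7 (2.23, SE 0.40), DREB2A (3.82, SE 0.40), ADS2 (2.84, SE 0.43) and BAM3 (2.98, SE 0.55). No member of the other 6 lists passed, also when adjusted over the list alone. The median was below 0 with an upward camera direction for abscisic acid (-0.06, mean 0.52), heat shock (-0.04, mean 0.39), membrane lipids (-0.02, mean 0.28) and ribosome biogenesis (-0.02, mean -0.02). In all, 1329 genes were higher and 499 lower (709 and 201 by at least 2-fold). The counts were 744 and 207 without the libraries outside the comparison, 865 and 227 without cbfs-1 0 h replicate 1, 648 and 156 without cbfs-1 0 h replicate 2, and 524 and 113 without cbfs-1 3 h replicate 1. With the replicate number as a block they were 2025 and 1038.

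At 24 h in cbfs-1 COR15B rose from 34.6 ± 15.4 to 5376 ± 174 (log2 change 7.31, SE 0.37, adjusted p = 3.93e-06), COR15A to 3183 ± 128 (4.54, SE 0.38) and RD29A to 10310 ± 1808 (4.11, SE 0.31). CBF3 was at 846 ± 66.7, CBF2 at 695 ± 348 and CBF1 at 58.4 ± 28.7, still above 0 h. Of 15 CBF target genes, 12 rose and 3 did not pass (14 when adjusted over the list alone, median 2.48, camera adjusted p = 1.0e-07, adjusted p = 0.37 with an estimated correlation). Of 6 ribosome biogenesis genes, 5 rose (6 when adjusted over the list alone, camera adjusted p = 0.0026, adjusted p = 0.37 with an estimated correlation). FIB2 changed by 1.76 (SE 0.19). Of 14 early cold transcription factor genes, 6 rose (6 when adjusted over the list alone, camera adjusted p = 0.0098, adjusted p = 0.49 with an estimated correlation). RVE2 changed by 3.16 (SE 0.55). Of 14 clock genes, 8 rose and 2 fell (8 and 2 when adjusted over the list alone, camera adjusted p = 0.023, adjusted p = 0.37 with an estimated correlation). PRR5 changed by 6.60 (SE 0.38). Of 11 flavonoid genes, 7 rose and 0 fell (8 when adjusted over the list alone, camera adjusted p = 0.033, adjusted p = 0.61 with an estimated correlation), including TT5 (1.96, SE 0.48) and the anthocyanin regulator genes TT8 (1.69, SE 0.25) and MYB75 (1.64, SE 0.40). Of 8 RNA chaperone genes, 5 rose (5 when adjusted over the list alone, camera adjusted p = 0.033, adjusted p = 0.37 with an estimated correlation), with GRP7 at 113880 ± 6255. Of 11 elongation growth genes, 6 fell and 1 rose (6 and 1 when adjusted over the list alone, camera adjusted p = 0.044, adjusted p = 0.49 with an estimated correlation). EXPA8 changed by -4.78 (SE 0.61).

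The camera test was not passed by the other lists in cbfs-1 at 24 h. Among them the gibberellin, sugar and osmolyte, salicylate and defence and CBF family genes passed fry (adjusted p = 0.00032, 0.022, 0.022 and 0.022). Of 11 gibberellin genes, 7 fell and 2 rose (7 and 2 when adjusted over the list alone, camera adjusted p = 0.075), and of 11 sugar and osmolyte genes, 6 rose and 1 fell (7 and 1 when adjusted over the list alone, camera adjusted p = 0.055), BAM3 at 3.54 (SE 0.55) and GOLS2 at -2.19 (SE 0.40) among them. Of 18 light-harvesting and Rubisco genes, 4 fell (4 when adjusted over the list alone, camera adjusted p = 0.055). LHCB4.2 changed by -1.60 (SE 0.23). Of 12 salicylate and defence genes, 5 rose and 2 fell (5 and 2 when adjusted over the list alone, camera adjusted p = 0.086). PR5 changed by 2.35 (SE 0.22). Abscisic acid, CBF regulators, jasmonate and CBF family had 4, 6, 3 and 3 higher and 3, 3, 2 and 0 lower members (4, 6, 2 and 3 higher and 3, 3, 2 and 0 lower when adjusted over the list alone). Heat shock, membrane lipids, reference genes, root markers and cell division had 2, 2, 1, 1 and 0 higher and 1, 2, 1, 4 and 2 lower members (the same numbers when adjusted over the list alone, with 2 lower for heat shock), and floral and seed markers had 0. For abscisic acid the median was -0.11 and the mean -0.05 with an upward camera direction, and for root markers both were 0.02 with a downward direction. In all, 5140 genes were higher and 4816 lower (48.2% of those tested), of which 1711 and 1819 by at least 2-fold.

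**Figure D2:**
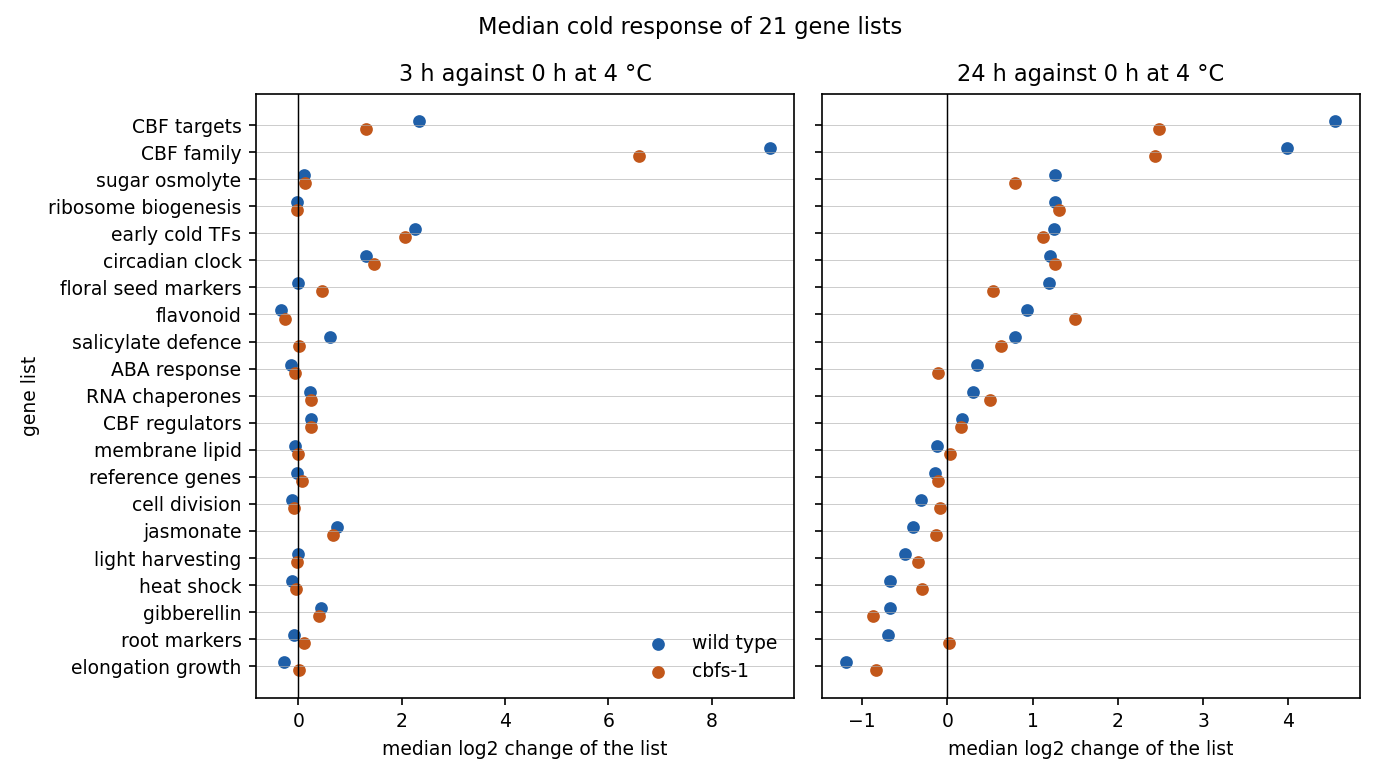
Median log2 change of each of the 21 gene lists after 3 h (left) and 24 h (right) at 4 °C against 0 h, in wild type and in cbfs-1. The CBF targets stood at 2.33 and 4.55 in wild type and at 1.31 and 2.48 in cbfs-1.

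Before cold, the comparison of cbfs-1 with wild type asked which genes already differed. CBF3 was higher in cbfs-1, at 157 ± 25.9 against 11.4 ± 5.44 (log2 difference 3.73, SE 0.36, adjusted p = 0.00785). The cold-regulated genes KIN1 and KIN2 were lower, at 176 ± 23.6 against 533 ± 99.4 (-1.59, SE 0.15) and at 684 ± 46.4 against 1595 ± 132 (-1.22, SE 0.11). ARP9, an actin-related protein gene, was lower at 231 ± 36.9 against 653 ± 9.30. AT3G41979, a 5.8S ribosomal RNA gene, and the retroelement SADHU5-1 were higher, at 200 ± 31.5 against a mean of 51.1 and at 162 ± 8.01 against 63.2 ± 7.99. MRD1 and AT1G67626, which fall outside the rule for named genes and were chosen after their values were seen, complete the 5 lower genes. MRD1 stood at 20.7 ± 4.71 in wild type and at 0 in both cbfs-1 libraries, and AT1G67626 at 27.2 against 0.473, which is under 3 reads. CBF1, under 3 reads in every 0 h library, and CBF2, at 37.7 ± 35.9 in cbfs-1 against 13.1 ± 15.4, did not pass.

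Of the lists, the CBF targets had 2 lower and 13 not passed members before cold (6 lower when adjusted over the list alone, median -0.21, camera adjusted p = 3.9e-08, adjusted p = 0.92 with an estimated correlation). The CBF family had CBF3 higher and 4 not passed (1 when adjusted over the list alone, camera adjusted p = 0.0062, adjusted p = 0.92 with an estimated correlation), and the abscisic acid genes had none passed but a camera call (adjusted p = 0.028, adjusted p = 0.92 with an estimated correlation). None of the lists named here passed fry (adjusted p = 0.97 for the CBF targets, the CBF family and the abscisic acid genes). No member of the other 18 lists passed, also when adjusted over the list alone. Median, mean and camera direction differed in sign for floral and seed markers, heat shock, RNA chaperones and salicylate and defence. In all, 3 genes were higher and 5 lower, with 677 at an unadjusted p below 0.05. With DESeq2 8 were higher and 8 lower, against 11 calls in simulated reads with no change, where limma and edgeR made 0, and with the replicate number as a block 5 and 8. None passed with the libraries of these groups alone or without cbfs-1 0 h replicate 1 or 2 or wild type 0 h replicate 2. Without wild type 0 h replicate 1 the counts were 1 and 0, and 1 gene was higher without either replicate of cbfs-1 at 3 h or at 24 h.

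After 3 h of cold, RD29A was lower in cbfs-1 than in wild type, at 1910 ± 411 against 13324 ± 4642 (log2 difference -2.77, SE 0.31, adjusted p = 0.0254). KIN2 was lower at 1392 ± 17.1 against 5466 ± 594 (-1.97, SE 0.11) and KIN1 at 234 ± 17.3 against 854 ± 70.5 (-1.86, SE 0.15). ARP9 was lower too (-1.36, SE 0.14). CBF3, at 1127 ± 45.1 against 6629 ± 702, did not pass (-2.55, SE 0.36, adjusted p = 0.0906), nor did CBF1 (0.37, SE 0.55) and CBF2 (0.44, SE 0.95). CBF3 was called in 9 of 23 other settings: with edgeR (0.043), DESeq2 (1.31e-13), the replicate number as a block (0.011), a block by time chosen after seeing the data (0.00229) and only these groups (0.0397). The other 4 of these were without wild type 0 h replicate 1 or 2 (0.0436 and 0.0431) or wild type 24 h replicate 1 or 2 (0.0227 and 0.0238). Of 15 CBF targets, 3 were lower and 12 did not pass (12 lower when adjusted over the list alone, median -1.37, camera adjusted p = 2.0e-38, adjusted p = 0.079 with an estimated correlation).

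The camera test was also passed downward at 3 h by the salicylate and defence genes (0 passed, 4 lower when adjusted over the list alone, median -0.32; adjusted p = 2.0e-08, adjusted p = 0.23 with an estimated correlation) and the jasmonate genes (0 passed; median -0.20; adjusted p = 0.0054, adjusted p = 0.51 with an estimated correlation). No member of the other 18 lists passed over all genes; adjusted over the list alone, 1 CBF family gene did. Median, mean and camera direction differed in sign for the CBF family (median 0.37, mean -0.13, downward), early cold transcription factors (0.05, -0.09, downward) and floral and seed markers (0.35, -0.21, upward). By limma 0 genes were higher and 6 lower, with 696 at an unadjusted p below 0.05. There edgeR called 1 and 5, DESeq2 11 and 41 (in simulated reads with no change limma and edgeR made 0 calls and DESeq2 14), and limma with the replicate number as a block 7 and 21. With only these groups 2 genes were lower, 0 of them among the 6. The lower genes numbered 1, 2, 3 and 1 without wild type 3 h replicate 1 or 2 or cbfs-1 3 h replicate 1 or 2, each of them among the 6. They numbered 15 without wild type 24 h replicate 1 or 2 and 3 without cbfs-1 24 h replicate 1 or 2. The higher genes numbered 1 without either replicate of wild type at 0 h or of wild type at 24 h.

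After 24 h of cold, CBF target genes were lower in cbfs-1 than in wild type. COR15A stood at 3183 ± 128 against 81402 ± 14000 (log2 difference -4.67, SE 0.38, adjusted p = 0.000946), GOLS3 at 435 ± 66.5 against 12792 ± 8549 (-4.70, SE 0.42) and RD29A at 10310 ± 1808 against 151190 ± 61530 (-3.82, SE 0.31). The dehydrin gene LTI30 (-3.34, SE 0.27) and KIN1 (-2.97, SE 0.15) were lower, and so were 3 genes outside the list, AT1G16850 (-4.04, SE 0.31), AT4G30830 (-4.00, SE 0.39) and AT4G25433 (-3.77, SE 0.44). By locus number AT4G25433 lies close to CBF2 (AT4G25470), and linkage was not tested for it. Of 15 CBF targets, 11 were lower and 4 did not pass (14 lower when adjusted over the list alone, median -2.43, camera adjusted p = 1.1e-35, adjusted p = 0.094 with an estimated correlation). Genes higher in cbfs-1 included CYP79B3 (613 ± 2.26 against 194 ± 15.3; 1.66, SE 0.09), CYP79B2 (1.47, SE 0.22) and CYP83B1 (1.34, SE 0.13), enzymes of indole glucosinolate synthesis. AT5G35935 (2.80, SE 0.24), AT3G41979 (1.69, SE 0.22), SADHU5-1 (1.38, SE 0.15), PYD4 (1.28, SE 0.23) and the anthocyanin enzyme gene DFR (1.46, SE 0.23) were also higher. CBF3, at 846 ± 66.7 against 292 ± 158, did not pass (1.64, SE 0.36, adjusted p = 0.0885), nor did CBF1 (0.45, SE 0.55) and CBF2 (0.81, SE 0.95). CBF3 was called in 4 of 23 other settings. These were DESeq2 (adjusted p = 0.000114), limma with the replicate number as a block (0.0194) or with a block by time chosen after seeing the data (0.0044), and limma without wild type 24 h replicate 1.

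**Figure D3:**
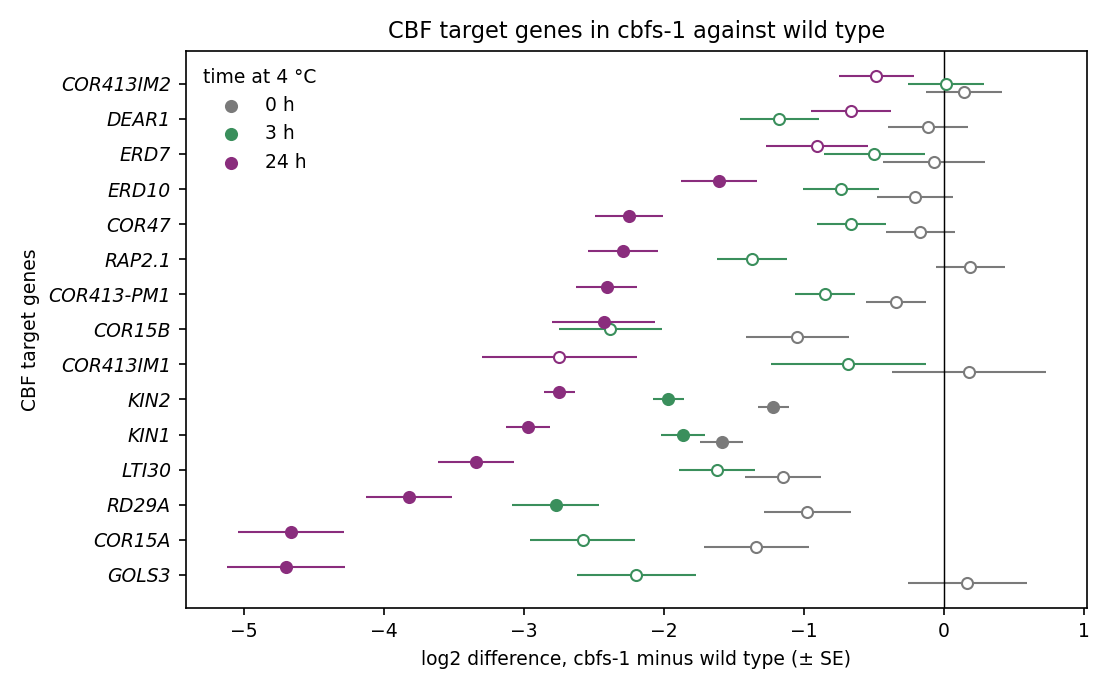
Log2 difference of cbfs-1 minus wild type (± SE) of the 15 CBF target genes at 0 h, 3 h and 24 h at 4 °C; filled points passed the test over all genes and open points did not. At 24 h 11 points are filled, and the list's median is -2.43.

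Of 11 sugar and osmolyte genes at 24 h, SUS1 was lower in cbfs-1 (3466 ± 554 against 16039 ± 5855; -2.17, SE 0.21) and 10 did not pass (5 lower when adjusted over the list alone, median -0.75, camera adjusted p = 8.7e-07, adjusted p = 0.27 with an estimated correlation). Of 11 flavonoid genes, DFR was higher and 10 did not pass (3 higher when adjusted over the list alone, camera adjusted p = 0.0073, adjusted p = 0.59 with an estimated correlation). With no member passing over all genes, the camera test was passed downward by the abscisic acid genes (1 lower when adjusted over the list alone; adjusted p = 0.0045, adjusted p = 0.59 with an estimated correlation) and upward by the cell division genes (0 when adjusted over the list alone; adjusted p = 0.016, adjusted p = 0.34 with an estimated correlation). The other 16 lists had no member past the test over all genes; adjusted over the list alone, 1 gibberellin gene was higher and 2 lower, and 1 root marker and 1 CBF family gene were higher. The reference genes had a median of 0.07 and a mean of 0.01 with a downward camera direction.

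At 24 h 55 genes were higher and 112 lower in cbfs-1, of which 18 and 77 by at least 2-fold, with 2154 at an unadjusted p below 0.05. These counts are without a block. The replicate number as a block gave 504 calls, and the block by time, chosen after seeing the data, gave 1257. Deviations of same-numbered libraries correlated at 0.242 between the 24 h groups, which form 1 pair. Of the 112, 94 (83.9%) were among the 5305 genes that rose in wild type, against 28.8 for independent lists. Of the 55, 43 (78.2%) were among the 5022 that fell in wild type, against 13.4 for independent lists. In 100 simulations with no genotype effect the mean overlaps were 0.03 and 0.02, with a mean of 0.06 and 0.03 genes called between the genotypes. They hold too few calls to set a level for 112 and 55 genes. Both comparisons use the wild type 24 h libraries, so part of the excess may come from shared controls; each part of a split would hold 1 library. At 3 h 4 of 6 lower genes had risen in wild type, against 0.413 for independent lists (simulated mean 0.03, with 0.05 genes called), and the overlap in the other direction was 0, as no gene was higher in cbfs-1 at 3 h. With the replicate number as a block the 3 h overlaps were 17 and 4. The counts at 24 h were 9 and 18 without cbfs-1 24 h replicate 2, 10 and 18 without cbfs-1 24 h replicate 1 and 23 and 30 without wild type 24 h replicate 1, and the overlaps then were 15, 15 and 28 for the lower genes and 9, 9 and 21 for the higher. DESeq2 called 126 and 224. In simulated reads with 200 changed genes, limma called 168 of these and 12 unchanged genes, edgeR 168 and 13, and DESeq2 167 and 30. With only these groups 32 were higher, and 93 of its 141 calls were among the 167.

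The last comparison asked whether the cold response itself differed between genotypes. At 3 h CBF3 rose by 9.13 in wild type and by 2.85 in cbfs-1 (difference -6.28, SE 0.51, adjusted p = 0.00788). The higher level of CBF3 in cbfs-1 before cold made up the larger part of this difference. By limma 0 genes were higher and 1 lower, also with the replicate number as a block, with 309 at an unadjusted p below 0.05 without it. The edgeR test called 0 and 1, DESeq2 0 and 3 (in simulated reads with no change limma made 0 calls, edgeR 1 and DESeq2 8), and a block by time, chosen after seeing the data, 0 and 6. At 24 h KIN2 rose by 5.32 in wild type and by 3.79 in cbfs-1 (difference -1.53, SE 0.16, adjusted p = 0.032), and CYP79B3 changed by -2.78 and -1.12 (difference 1.66, SE 0.13, adjusted p = 0.005). By limma without a block 1 gene was higher and 1 lower, with 966 at an unadjusted p below 0.05. The replicate number as a block gave 75 calls and the block by time 261. The edgeR test called 1 and 0 and DESeq2 20 and 71. For this difference in simulated reads with 200 changed genes, limma called 126 of these and 12 unchanged genes, edgeR 124 and 9, and DESeq2 134 and 26. CBF1, with under 3 reads in each 0 h library, and CBF2, with 2 reads in wild type 0 h replicate 2 and more in the others, did not pass at either time. CBF3 did not pass at 24 h (-2.08, SE 0.51, adjusted p = 0.447), and was called there in 2 of 23 other settings, DESeq2 (0.0103) and limma with the block by time (0.0225).

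The CBF targets responded less to 24 h of cold in cbfs-1, with 1 gene passing over all genes (12 lower when adjusted over the list alone, median difference -2.07; fry adjusted p = 0.04, camera adjusted p = 2.2e-33, adjusted p = 0.11 with an estimated correlation). At 3 h none passed (4 lower when adjusted over the list alone, median -0.75, camera adjusted p = 2.0e-18, adjusted p = 0.41 with an estimated correlation). The camera test was also passed at 3 h by the salicylate and defence genes (median -0.29; adjusted p = 4.5e-06, adjusted p = 0.43 with an estimated correlation) and the CBF family, of which CBF1, CBF4 and DDF1 lay under 3 reads at 0 h (adjusted p = 0.02, adjusted p = 0.94 with an estimated correlation). The jasmonate genes passed it with the replicate number as a block (median -0.13; adjusted p = 0.0277, adjusted p = 0.495 with an estimated correlation, and adjusted p = 0.32 without the block). At 24 h it was passed by the sugar and osmolyte genes (median -0.63; adjusted p = 1.5e-05, adjusted p = 0.40 with an estimated correlation), the flavonoid genes (median 0.58; adjusted p = 0.0025, adjusted p = 0.58 with an estimated correlation) and the root markers (median 0.24; adjusted p = 0.017, adjusted p = 0.46 with an estimated correlation). Adjusted over the list alone, 1 CBF family gene was lower at 3 h, and at 24 h 2 flavonoid genes and 1 root marker were higher and 2 sugar and osmolyte genes and 1 CBF family gene lower. Median, mean and camera direction differed in sign for floral and seed markers at 3 h (0.14, -0.20, downward) and reference genes at 24 h (-0.00021, 0.04, upward).

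Across the 20666 genes, which are not independent replicates, the responses of the genotypes correlated at 3 h with Pearson's r 0.883 and Spearman's rho 0.760, and at 24 h with 0.920 and 0.910; the responses share no library. The slope of the cbfs-1 response on the wild type response was 0.846 at 3 h and 0.872 at 24 h. Of the 2087 genes called in wild type at 3 h, 99.2% had the same sign in cbfs-1 and 1469 were called in the same direction. Of the 10327 called at 24 h, 98.7% had the same sign and 8341 were called in the same direction. The CBF3 difference at 3 h was not called without wild type 3 h replicate 1 or 2 (adjusted p = 0.0509 and 0.0675), cbfs-1 0 h replicate 2 (0.0522) or cbfs-1 3 h replicate 1 or 2 (0.0632 and 0.0700). The CYP79B3 call ended without cbfs-1 0 h replicate 1 or cbfs-1 24 h replicate 1 or 2 (0.0589, 0.0708 and 0.0737), and the KIN2 call without either replicate of wild type 0 h, cbfs-1 0 h, cbfs-1 3 h or cbfs-1 24 h (0.0950 to 0.334); both ended with only the compared groups (0.0569) and the KIN2 call with edgeR (0.0533).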

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

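The cold responses below were singled out because the difference between the genotypes, tested directly, passed the threshold with limma for genes and with fry for lists. Other lists, named in the results above, passed camera at the preset correlation but not fry. Of the 23 other settings, the replicate block by time was chosen after the result was seen.

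CBF3 rose by 9.13 in wild type and 2.85 in cbfs-1 after 3 h on the log2 scale, a difference of -6.28 (SE 0.51, limma adjusted p = 0.00788). Over the 23 settings the difference ran from -6.74 to -5.82, with the call lost in 5, in which 1 library was left out: wild type 3 h replicate 1 (adjusted p = 0.0509) or 2 (0.0675), cbfs-1 0 h replicate 2 (0.0522), and cbfs-1 3 h replicate 1 (0.0632) or 2 (0.0700). The larger part of it lay before cold, where CBF3 stood at 157 ± 25.9 in cbfs-1 and 11.4 ± 5.44 in wild type (SD, n = 2). After 3 h cbfs-1 differed from wild type by -2.55, which did not pass in the main fit and was called in 9 of the 23 other settings.

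CYP79B3 changed by -2.78 in wild type and -1.12 in cbfs-1 after 24 h, a difference of 1.66 (SE 0.13, adjusted p = 0.005). Over the 23 settings the difference ran from 1.56 to 1.76, and the call was lost in 4: with only the compared groups (0.0569) and without cbfs-1 0 h replicate 1 (0.0589) or cbfs-1 24 h replicate 1 (0.0708) or 2 (0.0737). KIN2 changed by 5.32 and 3.79, a difference of -1.53 (SE 0.16, adjusted p = 0.032). It ran from -1.65 to -1.41, and its call was lost in 10 of 23 settings: with edgeR (0.0533), with only the compared groups (0.0569), and without wild type 0 h replicate 1 (0.232) or 2 (0.0964), cbfs-1 0 h replicate 1 (0.206) or 2 (0.0950), cbfs-1 3 h replicate 1 (0.103) or 2 (0.102), or cbfs-1 24 h replicate 1 (0.334) or 2 (0.287). In simulated reads with 200 changed genes, limma called 126 of these and 12 unchanged genes for the difference in the 24 h response.

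The 15 CBF targets as a list responded less in cbfs-1 after 24 h, with a median difference of -2.07 (fry adjusted p = 0.04; camera adjusted p = 2.2e-33, adjusted p = 0.11 with an estimated correlation).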

How the results depend on the processing

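The alternatives were planned except the block by time, which was chosen after seeing the data. Of the results for named genes over contrasts and settings, 6596 stayed on the same side of the threshold, 350 lost the call, 15 gained one and 0 of the called ones reversed. The lack of reversals was in part fixed by the rule for naming genes. The largest changes between 2 groups were named only where both libraries of a group lay above both of the other. Leaving out 1 library could therefore not reverse them, and leaving out a library outside a contrast did not change its log2 value. For gene lists 4199 stayed on the same side, 36 lost the call, 103 gained one, and 9 that were called under either setting changed sign or went to 0. Where a setting leaves a group with 1 library, that library is assumed to vary like the other groups. Such settings, and those with only the compared groups, hold fewer libraries, and the filter settings test other numbers of genes. For the other changes the cause was not tested. TMM scaling and quantile normalization moved the share of higher calls by under 10 percentage points, and the median of all genes by under 0.1 log2 units. Depth limited genes near the floor of 3 reads: CBF1 had 2 and 1 reads at 0 h in wild type and 1 and 2 in cbfs-1.

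Calls of at least 2-fold numbered 784 higher and 257 lower in wild type at 3 h, and 1838 and 1933 at 24 h. In cbfs-1 they numbered 709 and 201 at 3 h, and 1711 and 1819 at 24 h, and 18 genes were higher in cbfs-1 than in wild type at 24 h. With only the compared groups the counts were 631 and 137 in wild type and 744 and 207 in cbfs-1 at 3 h. Between the genotypes they were then 0 and 0 at 0 h, 2 lower at 3 h with 0 shared with the 6, and 32 higher at 24 h, where 93 of 141 calls were shared with the 167, and 0 and 0 for the difference in the 24 h response. The overlap of genes that rose in wild type at 3 h with those lower in cbfs-1 was then 2, and that of genes that fell at 24 h with those higher in cbfs-1 was 21. DESeq2 called 8 and 8 genes between the genotypes at 0 h, 11 and 41 at 3 h and 126 and 224 at 24 h. For the difference in response it called 3 lower at 3 h, and 20 and 71 at 24 h. Its overlaps were 26 and 3 at 3 h and 177 and 91 at 24 h. With edgeR 1 gene was higher between the genotypes at 3 h and 0 were lower for the difference in the 24 h response. A filter at 50 left 3 lower genes at 0 h. The correlation of the responses was 0.751 at 3 h and 0.856 at 24 h without a filter, and 0.929 and 0.943 with the filter at 50. At 24 h it was 0.917 and 0.929 with pseudocounts of 0.5 and 5, 0.912 with edgeR and 0.913 with DESeq2.

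With the replicate block, 2169 genes were higher and 1286 lower in wild type at 3 h, and 2025 and 1038 in cbfs-1. Between the genotypes the replicate block gave 5 and 8 at 0 h, 7 and 21 at 3 h and 237 and 267 at 24 h, and 16 and 59 for the difference in the 24 h response. The overlaps were 17 and 4 at 3 h and 215 and 178 at 24 h. The block by time gave 2898 and 2253 in wild type and 2751 and 1947 in cbfs-1 at 3 h. Between the genotypes it gave 20 and 15 at 0 h, 21 and 67 at 3 h and 650 and 607 at 24 h, with 6 lower for the difference in the 3 h response and 70 and 191 for the 24 h response. Its overlaps were 47 and 7 at 3 h and 421 and 404 at 24 h, and its 24 h correlation was 0.927. In the comparisons of 0 h and 3 h groups the replicate block changed the call of 1 named gene, CBF3 between the genotypes at 3 h (adjusted p = 0.011), and of 1 list, the jasmonate genes for the difference in the 3 h response (adjusted p = 0.0277), and no other call of a named gene or list. Deviations of same-numbered libraries correlated at 0.0428 to 0.108 in the 8 pairs of a 24 h group with an earlier group, and at 0.242 in the 1 pair of 24 h groups. Not every pair with a 24 h group was over 0.1, so the numbers are not taken to pair the 24 h libraries with the others, unlike the 0 h and 3 h groups. This is a hint from the data, not the design.

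Leaving out each library in turn gave 712 to 1380 higher and 162 to 620 lower genes in wild type at 3 h. These were 712 and 162 without wild type 3 h replicate 1, 758 and 201 without wild type 0 h replicate 2, and 339 lower without its replicate 1. In cbfs-1 at 3 h the ranges were 524 to 1354 and 113 to 516, with 524 and 113 without cbfs-1 3 h replicate 1, 648 and 156 without cbfs-1 0 h replicate 2 and 865 and 227 without its replicate 1. At 24 h they were 3798 to 5330 and 3681 to 5023 in wild type and 3460 to 5195 and 3244 to 4821 in cbfs-1. The correlations ran from 0.825 to 0.883 at 3 h and from 0.892 to 0.920 at 24 h.

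Between the genotypes at 0 h, leaving out each library gave 0 to 3 higher and 0 to 5 lower genes. The higher genes numbered 1 without wild type 0 h replicate 1 or any cbfs-1 library at 3 h or 24 h, and 0 without the other 0 h libraries. The lower genes numbered 0 without any 0 h library. At 3 h the ranges were 0 to 1 and 1 to 15. The value of 1 higher came without either wild type library at 0 h or 24 h. The lower genes numbered 15 without either wild type 24 h library, 1 and 2 without wild type 3 h replicates 1 and 2, 3 and 1 without cbfs-1 3 h replicates 1 and 2, and 3 without either cbfs-1 24 h library. At 24 h they were 9 to 57 and 18 to 154, with 23 and 30 without wild type 24 h replicate 1, 10 and 18 without cbfs-1 24 h replicate 1 and 9 and 18 without its replicate 2. The overlaps ran from 1 to 13 and 0 to 1 at 3 h and from 15 to 140 and 9 to 44 at 24 h. At 3 h the first was 13 without either wild type 24 h library, 7 without wild type 0 h replicate 1, 1 without wild type 3 h replicate 1 or cbfs-1 3 h replicate 2, and 2 without their partners or either cbfs-1 24 h library, and the other was 1 without either wild type 0 h library. At 24 h they were 28 and 21 without wild type 24 h replicate 1 and 15 and 9 without either cbfs-1 24 h library.

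For the difference in the 3 h response the ranges were 0 to 0 and 0 to 2. The lower genes numbered 2 without cbfs-1 0 h replicate 1 and 0 without cbfs-1 0 h replicate 2 or any 3 h library. For the 24 h response they were 0 to 5 and 0 to 49. Without wild type 24 h replicate 1 the counts were 5 and 4, and without its replicate 2 they were 4 and 49. The higher genes numbered 0 without cbfs-1 0 h replicate 1 or either cbfs-1 24 h library. The lower genes numbered 2 without either wild type 3 h library, and 0 without either wild type 0 h library, cbfs-1 0 h replicate 1, or any cbfs-1 library at 3 h or 24 h.

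Of the 4347 list results under other settings, 206 medians had the opposite sign, 198 of them with no call of the list by camera under either setting. The other 8 came from 5 lists in a contrast. Between the genotypes at 0 h, leaving out each library gave -0.142 to 0.168 for the salicylate and defence genes, with -0.105 and a call without cbfs-1 0 h replicate 2, and -0.142 with no call without wild type 0 h replicate 2. At 3 h the flavonoid genes gave -0.624 to 0.444, with 0.444 and a call without wild type 3 h replicate 2. For the difference in the 3 h response the CBF family, with 3 members under 3 reads at 0 h, gave 0.107 with a pseudocount of 5. Leaving out each library gave -0.722 to 0.343, with 0.343 without wild type 0 h replicate 2, 0.165 without wild type 3 h replicate 2 and 0.190 without cbfs-1 3 h replicate 1, and in these 4 settings the call was lost. For the 24 h response the abscisic acid genes gave -0.611 to 0.211, with 0.211 and a call without wild type 24 h replicate 1. The salicylate and defence genes gave -0.189 to 0.211, with 0.211 and a call without cbfs-1 0 h replicate 2. The CBF family between the genotypes at 0 h gave 0 to 0.993, and lost its call at a median of 0, which has no direction, without wild type 0 h replicate 2.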

Other observations

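All gene lists and tests in this part were chosen after the result was seen, and their p-values were adjusted over 18 tests (2 lists in 9 contrasts).

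Of 23 genes of glucosinolate synthesis, which makes sulfur-containing defence compounds, 10 fell and 0 rose in wild type at 3 h (median log2 change -0.38, camera adjusted p = 1.2e-06, adjusted p = 0.18 with an estimated correlation). At 24 h 17 fell and 0 rose (median -0.62, camera adjusted p = 1.0e-06, adjusted p = 0.18 with an estimated correlation). In cbfs-1 6 fell at 3 h, and at 24 h 3 fell and 2 rose (median -0.05, camera adjusted p = 0.23). Between the genotypes at 24 h 8 were higher in cbfs-1 by limma, 8 by edgeR and 13 by DESeq2, and 22 of 23 had a positive difference (median 0.64, camera adjusted p = 6.0e-28, adjusted p = 0.025 with an estimated correlation). The 8 were CYP79B2, CYP79B3, CYP83B1 and SOT16 and, from the methionine-derived branch, CYP79F2 (866 ± 55.5 against 438 ± 32.8, SD, n = 2), IMS2, BCAT4 and IMD1. The difference in the 24 h response had a median of 0.53 (camera adjusted p = 2.8e-28, adjusted p = 0.025 with an estimated correlation), and CYP79B3 alone passed over all genes by limma without a block. Root markers moved the same way, with a median of 0.24 for this difference (camera adjusted p = 0.017, adjusted p = 0.46 with an estimated correlation). Of 11, 6 fell and 0 rose in wild type at 24 h, and 4 fell and 1 rose in cbfs-1. Leaving out each library gave medians of 0.52 to 0.69 between the genotypes. Without wild type 24 h replicate 1 or cbfs-1 24 h replicate 1, 4 genes were called, and without cbfs-1 24 h replicate 2, 3 genes.

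Of 16 genes induced by sulfur starvation, 7 fell and 0 rose at 3 h in wild type (camera adjusted p = 1.1e-07, adjusted p = 0.073 with an estimated correlation) and 7 fell and 0 rose in cbfs-1 (camera adjusted p = 1.6e-08, adjusted p = 0.073 with an estimated correlation). In wild type LSU1 changed by -3.62 (SE 0.45), AT1G04770 by -3.28 (SE 0.37) and the sulfate reduction gene APR1 by -1.22 (SE 0.18). At 24 h 10 fell and 2 rose in wild type (camera adjusted p = 0.0046, adjusted p = 0.25 with an estimated correlation), and 9 fell and 2 rose in cbfs-1 (camera adjusted p = 0.026, adjusted p = 0.31 with an estimated correlation). Between the genotypes at 24 h 0 passed by limma or edgeR and 1 by DESeq2, with 5 at an unadjusted limma p below 0.05 (median 0.44, camera adjusted p = 3.9e-05, adjusted p = 0.16 with an estimated correlation). Before cold 0 passed by limma, and 13 of 16 differences were positive (median 0.14, camera adjusted p = 0.035, adjusted p = 0.32 with an estimated correlation). The difference in the 24 h response had a median of 0.12 (camera adjusted p = 0.0074, adjusted p = 0.26 with an estimated correlation).

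The higher level of glucosinolate genes in cbfs-1 at 24 h was weighed against 3 other explanations. A larger share of root tissue would raise root markers as much. At 24 h their median difference was smaller, 0.11 against 0.64 (standard error of the difference 0.13). For the difference in the 24 h response the medians were 0.24 and 0.53 (standard error 0.16). These standard errors run across genes, which are not independent replicates, so they cannot decide on a root share. A uniformly smaller response, with the slope of 0.872 over all genes, left a median of 0.45 (SE across genes 0.07). As the list was chosen after its values were seen, this remainder may in part be set by that choice. With TMM scaling and quantile normalization, tried for an effect of scaling between libraries, the medians were 0.63 and 0.64. Besides a root share, a part of CBF function in the lower level of these genes, found and tested on the same data, and another difference of the 1 mutant line stay open as hypotheses.

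Replicates 1 and 2 differed in a shared way in the 0 h and 3 h groups of both genotypes. Sampling at another time of day would set morning and evening clock genes apart, and the median of the morning genes minus that of the evening genes, in replicate 1 against replicate 2, was -1.69 and -1.22 at 0 h and -2.64 and -2.48 at 3 h in wild type and cbfs-1. At 24 h it was -0.17 and -0.09. Sequencing depth is argued against, as the wild type 0 h replicates, with a depth ratio of 0.999, shared the difference with the other 3 groups (lowest correlation across genes 0.39). The time of sampling is not given in the sources used here, and no biological explanation was tested.

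Besides CBF3 and CBF targets, 5 genes differed between the genotypes before cold: MRD1, AT1G67626, AT3G41979, SADHU5-1 and ARP9. Loss of cold-induced CBF activity would make the difference grow with cold. In AT3G41979, SADHU5-1 and ARP9 its size grew by a median of 0.03 from 0 h to 24 h. The SE of 0.15 runs across these genes, which are not independent replicates. For KIN1 and KIN2, which were called at 0 h in the same way, the size grew by 1.38 and 1.53. For MRD1, with 158 reads in 6 wild type libraries and 1 in 6 cbfs-1 libraries, and AT1G67626, with 143 and 21, the median of -0.52 decides nothing, as these genes lay near the floor. Linkage to the CBF cluster on chromosome 4 is argued against for 4 of the 5 genes, which lie on other chromosomes. SADHU5-1 lies on chromosome 4 but 2066 gene rows from CBF2, not close to the cluster. Of 34 tested genes within 20 gene rows on either side of the cluster, 0 were called at 0 h, 1 at 3 h and 2 at 24 h. Over all genes 0.0387%, 0.0290% and 0.808% were called. Linkage was not tested for the genes called at 3 h or 24 h, such as AT4G25433, which lies close to CBF2 by locus number. Another genetic or epigenetic difference of the mutant line cannot be told apart from a CBF effect at 0 h, since all 5 genes had the same sign of the difference at each time and 1 mutant line was sequenced.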
